A study of Mus musculus with 6 samples.

How the data were processed

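RNA from the stomach antrum of mice of 3 strains was measured on Affymetrix expression arrays, with 2 arrays each for C57/BL6 (here BL6), Beige and Satin. Total RNA was extracted with Trizol and labelled as biotinylated cRNA, per the labels' protocols. The deposited values are linear intensities, 1 signal per probe set and array, in 1 table of 22690 probe sets. The algorithm that turned probe intensities into these signals, any scaling between arrays, and detection calls are not given in the sources used here. The medians of the 6 columns ranged from 38.2 to 74.15, and the sorted columns differed by up to 0.78 on the log2 scale, so no common distribution had been imposed on them. Of the sample columns 0 were left unused.

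Each array was assigned to its strain and replicate number from its title. The design text speaks of 2 mice of each strain, without stating that each array holds RNA of 1 animal. The p-values therefore measure the spread between these arrays, which may be partly technical. No array date or batch is given in the sources used here, and the genetic backgrounds of the Satin and Beige mice are not given there either. All 15 pairs of arrays differed in nearly all of their values (35 to 88 equal values per pair), so no array had been entered under more than 1 sample.

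The 64 Affymetrix control probe sets were left out of all tests. Signals were converted to log2(signal + 32) and quantile normalized between arrays. A difference on this scale understates the change of dim genes. Of the 22626 other probe sets, 20380 carried a single gene symbol in the platform annotation, 691 carried several and 1555 were not listed. Through their gene ID, 20351 of the single-symbol probe sets were found in a reference gene table of the mouse assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and chromosome membership only. Of several probe sets of a gene, the one with the highest mean over the 6 arrays was used, which gave 12393 genes. Genes with a mean within the lowest 30% of all probe sets that are not controls (below 5.74 on the log2 scale) were left out, which left 9395 genes tested. The 1292 probe sets past this filter without a single symbol were tested apart and are not named.

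Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the intensity trend, two-sided) in 1 fit of the 6 arrays with strain as the only factor. The fit had 3 residual degrees of freedom and 9.24 after moderation. Satin was compared with the mean of BL6 and Beige, with Beige and with BL6, and Beige was compared with BL6. Below, "against both controls" means against the mean of the 2 control strains. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors are standard errors (SE) of the fitted difference or SDs of the 2 arrays of a strain, except for medians over genes. For those the SE comes from the spread between the genes. It treats them as independent, though they were measured on the same arrays, and can be too small. The number of arrays, 2 per strain, limits the precision.

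The overlap of the calls against each control strain was set beside 100 simulations of unchanged groups that share the Satin arrays, and beside the overlap of independent lists. Whether calls gathered on a chromosome was tested with Fisher's exact test, two-sided, for each of 22 chromosomes. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. There were 33 lists of marker genes and pathway genes, with 683 members, of which 587 were on the array and 518 were tested. In addition, the members of each list were adjusted over the list alone. A list needed 4 tested members for camera, which 32 lists had.

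The groups, comparisons, tests, filter, lists, the first set of other settings given below and the rule for named genes were fixed before the data were examined. By that rule the text names genes from a fixed panel of gastric genes, Foxq1, Lyst and Xist, from the calls of each comparison (up to 12 with the largest differences in each direction, or the 5 with the smallest p where none was called), from the lists described (up to 4 called members of each list, or 2 by p where none was called) and from the 12 genes in each direction with the largest smaller difference against the control strains taken singly. Muc6 and Ddx3y have no single-gene probe set and are not analysed here. Any other gene named was chosen after its values were seen. Matching of old gene symbols to list members was corrected after the first matches had been looked at, so that a current symbol of another gene is not read as an old one.

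The fit and the calls were tested on simulated values with 200 of 9395 genes changed in each of 10 runs. A further short list was shifted in Satin and counted as changed too. Noise was drawn independently for each gene on the normalized scale. Normalization, filter and choice of probe set were therefore not tested. Where arrays deviate in many genes at once, recovery may be lower and false calls more frequent. In Satin against both controls, 64.2% of genes with a difference of 1 on the log2 scale were recovered, 89.8% at 1.5, 97.2% at 2 and 100% at 3, and 6.6% of calls were false. Against Beige the recovery was 48.4%, 78.4%, 92.6% and 99.2%, with 6.07% of calls false, and against BL6 it was 47.6%, 79.8%, 93.0% and 99.6%, with 7.18% false. Also chosen before the data were examined were pseudocounts of 1 and 100, the values as deposited, median centring, no filter and a 50% filter, each probe set on its own, the mean of a gene's probe sets, eBayes without the trend and with its robust option, only the strains compared in the fit, the replicate number as a block, each array left out in turn, and camera with an estimated correlation. Median centring was first computed on linear values, and after its counts were seen it was changed to centre log2 values, as had been planned. Chosen after seeing the data were scaling to 9 bacterial and phage hybridization control probe sets, the mean of the pancreatic acinar genes as a covariate, the ratio of the 5' to the 3' Gapdh control probe set as a covariate, and a fit of 4 arrays without replicate 2 of BL6 and of Satin. In the last, the remaining single arrays are assumed to vary like the Beige pair.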

Results

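The series addressed gastric cell lineages in relation to FOXQ1, a forkhead transcription factor. Satin mice carry a mutation in Foxq1, and Beige mice, a second coat colour strain, carry a mutation in Lyst. Antral RNA of Satin mice was compared with that of Beige and C57/BL6 (BL6) mice, both titled as controls, on 2 arrays per strain. Median signals were 47.6 and 38.2 on the BL6 arrays, 49.5 and 49.1 on the Beige arrays, and 74.15 and 58.6 on the Satin arrays. The hybridization control signal was 902 and 1145 in BL6, 836 and 937 in Beige, and 897 and 883 in Satin. The ratio of the 5' to the 3' Gapdh probe set, a measure of RNA integrity, was 0.526 on BL6 replicate 1 and lay between 0.988 and 1.18 on the other arrays. Correlations between arrays, across genes, ran from 0.897 to 0.954, and by correlation the arrays did not all group by strain. The first principal component held 33.4% of the variance. On it the Satin arrays lay at 19.2 and 24.6, and the control arrays between -30.8 and 8.44. On the second, with 25.0%, the Satin arrays lay apart, at -28.7 and 1.83. The 2 arrays of a strain correlated at 0.907 in BL6, 0.943 in Beige and 0.944 in Satin. Between BL6 and Beige, BL6 and Satin, and Beige and Satin, the replicate 2 arrays correlated at 0.954, 0.943 and 0.948. For the replicate 1 arrays the values were 0.919, 0.902 and 0.911.

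Foxq1 itself was measured in every sample, at 10.17 ± 0.03 (mean and SD of log2(signal + 32), n = 2) in BL6, 9.66 ± 0.35 in Beige and 10.46 ± 0.03 in Satin. Its difference of 0.54 (SE 0.16) between Satin and the mean of both controls did not pass the test (adjusted p = 0.167). With the arrays as deposited or scaled to the hybridization controls it did, with a difference of up to 1.13 and an adjusted p down to 0.00093. In these 2 settings the median of all genes was itself 0.43 and 0.50 higher in Satin, so part of that difference is shared by the bulk of genes. A transcript level does not check a mutation of the gene, so Foxq1 gives no check of the labels. Lyst lay near the filter in all strains, with a difference of -0.68 (SE 0.31, adjusted p = 0.401) in Satin. Xist, which marks female tissue, was near the filter in all strains at 6.13, 6.02 and 5.92.

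Compared with both control strains, the Satin antrum had far less Muc5ac transcript, which encodes the gel-forming mucin of surface mucous cells. It fell by 4.32 on the log2 scale (SE 0.15, adjusted p = 1.35e-06), from 12.89 ± 0.32 in BL6 and 12.95 ± 0.00 in Beige to 8.60 ± 0.01 in Satin, as measured by a single probe set. Fabp2, an intestinal fatty acid binding protein, fell by 4.63 (SE 0.20, adjusted p = 4.71e-06), from 11.11 in the controls to 6.48. The largest rise was that of Chil4, a chitinase-like lectin, by 6.47 (SE 0.23, adjusted p = 1.35e-06), from 7.08 in BL6 and 5.89 in Beige, near the filter, to 12.96. No exact fold is given, and the Chil4 differences here and below can be understated, since the controls lie near the filter and Satin near the top of the range. Bpifb1, a secreted protein of mucous glands, rose by 4.38 (SE 0.46, adjusted p = 0.00215), with 10.70 ± 1.45 in Satin, and Pga5, a pepsinogen, rose by 3.11 (SE 0.22, adjusted p = 0.00021).

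Other genes with large rises were Cldn3, a tight junction claudin (4.09, SE 0.49), Cap1, an actin regulator (3.61, SE 0.22), and Igha, the heavy chain of immunoglobulin A (3.34, SE 0.33). Smaller rises were those of Scd1, a fatty acid desaturase (2.12), the heat shock gene Hspa1b (2.06), Jchain, the joining chain of immunoglobulin A (2.00), Sdc4, a syndecan (1.90), the neutrophil protein gene S100a8 (1.85) and the carboxylesterase gene Ces1g (1.78). Large falls included Cybrd1, a ferric reductase (-2.84, SE 0.21), Rpgrip1 (-2.72), the kinase gene Stk25 (-2.59), Slurp1 (-2.53), C1qtnf12 (-2.37), Chgb, a secretory granule protein (-2.35), and Hsd17b2, a steroid dehydrogenase (-2.19). Also lower were Krt7, an epithelial keratin (-2.15), Adh7, a retinol and ethanol dehydrogenase of the stomach (-2.04), and Ly6g6c (-2.04). Further probe sets of Cldn3, Cap1, Igha, Hspa1b and Bpifb1 differed by 1.91 to 4.78 in the called direction, while a dimmer probe set of Sdc4 gave -0.52, one of Rpgrip1 gave -0.09 and one of Adh7 gave -0.82. Adjusted p rose above 0.05 for Cldn3 without Beige replicate 1 (0.0598) and Slurp1 without Beige replicate 2 (0.052). It did so for Scd1 without Beige replicate 1, Beige replicate 2 or Satin replicate 2 (0.11, 0.141 and 0.0983). The call of Hspa1b was lost without Beige replicate 1, Beige replicate 2 or Satin replicate 1 (0.165, 0.118 and 0.146). In the order Beige 1, Beige 2, Satin 1 and Satin 2 left out, the adjusted p was 0.132, 0.155, 0.113 and 0.088 for Jchain. In the same order it was 0.11, 0.0771, 0.193 and 0.204 for S100a8, and 0.112, 0.102, 0.381 and 0.084 for Ces1g. Calls were also lost in settings that left no single array out, for Bpifb1 in 1 (0.0752), Cldn3 in 2 (0.0962), Scd1 in 4 (0.156), Hspa1b in 4 (0.131) and Jchain in 5 (0.139), with the highest adjusted p in brackets. The same held for Sdc4 in 1 (0.175), S100a8 in 3 (0.134), Ces1g in 4 (0.167) and Rpgrip1 in 1 (0.175). Chgb is taken up with the endocrine genes.

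In all, 134 of 9395 genes were called in Satin against the mean of both controls, 40 higher and 94 lower, and 1179 had an unadjusted p under 0.05. Of the 134, 55 were also called against each control strain by itself. Of the calls, 95 exceeded a 2-fold and 20 a 4-fold difference. In each called gene both Satin arrays lay on one side of all 4 control arrays. The balance of directions depended on the scaling, with 1469 higher and 62 lower as deposited, 2440 and 57 when scaled to the hybridization controls, and 46 and 46 with median centring. Relative to the controls the median of all genes was shifted by 0.43 as deposited and by 0.50 with the hybridization controls, so the directions below are relative to the bulk of genes. The count was 299 without BL6 replicate 2, 34 without Beige replicate 1, 28 without Beige replicate 2 and 41 without Satin replicate 1. Under each of the 6 omissions 23 genes stayed called, 7 higher and 16 lower, among them Muc5ac, Fabp2, Chil4, Bpifb1, Pga5, Cap1 and Igha.

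**Figure D1:**
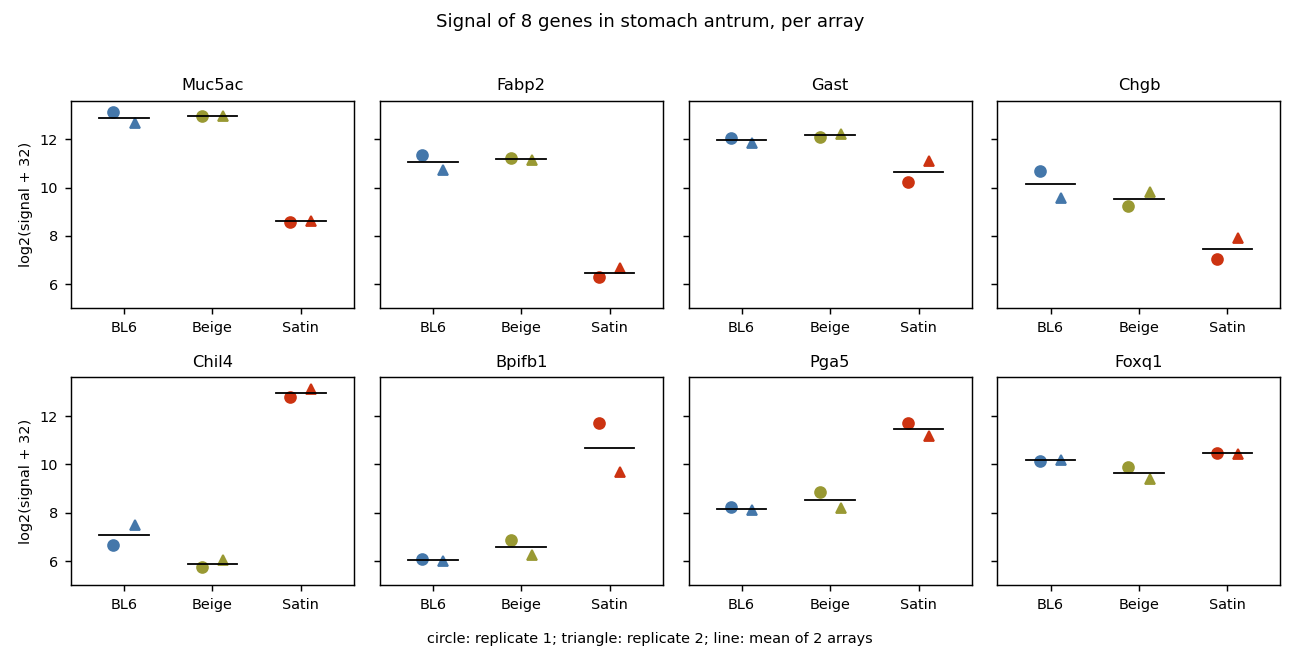
Signal of 8 genes per array, as log2(signal + 32) after quantile normalization, for the 2 arrays each of BL6, Beige and Satin (circle, replicate 1, and triangle, replicate 2), with the mean as a line. Muc5ac lies near 13 in both control strains and at 8.60 in Satin, Chil4 lies at or below 7.48 on the control arrays and at 12.96 on average in Satin, and Foxq1 lies between 9.41 and 10.49 throughout.

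Among 18 surface mucous (pit) cell markers, 2 fell, Muc5ac and Adh7, and 16 did not pass the test. Adjusted over the list alone, 1 rose and 4 fell. Members lay on both sides of 0, 8 above and 10 below (median -0.01), and Muc5ac and Adh7 made up most of the mean of -0.40. Camera placed the list lower (adjusted p = 0.0488), with an adjusted p = 0.47 with an estimated correlation. That call was lost without BL6 replicate 1 (0.058), BL6 replicate 2 (0.0634), Beige replicate 1 (0.09), Beige replicate 2 (0.0749) or Satin replicate 2 (0.251). It was also lost with a pseudocount of 100 (0.0502), with the mean of probe sets (0.0518), without the trend (0.102), in the 4 arrays (0.144) and with the Gapdh covariate (0.059). The replicate number as a block ended the pit cell call too. Relative to all genes, the pit median was -0.36 as deposited (camera adjusted p = 0.000336) and with median centring (0.000173), and -0.34 with the hybridization controls (0.00312). Markers at the top of the range can show too small a rise, which can lower the list relative to all genes. The pit markers with a control signal below 12, Muc5ac left out, had medians of 0.25, -0.08 and 0.33 in these settings. The medians of all genes were 0.43, 0.10 and 0.50. Gkn1, Gkn2 and Tff1, secreted products of the same cells, differed by -0.01, 0.03 and 0.10 (adjusted p = 0.981, 0.962 and 0.831). They ranked 3, 1 and 4 of all genes by control signal, at the top of the range, where a difference can be understated. Muc5ac ranked 11 in the controls, so its fall can be understated too.

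The 8 antral gland (deep mucous) cell markers all lay above 0, with a median of 0.33, and 1 rose, Bpifb1, also when adjusted over the list alone. Bpifb1, at 4.38, made up most of the list mean of 0.91, and the list was not tested without it. Camera placed the list higher (adjusted p = 0.000833, and adjusted p = 0.393 with an estimated correlation). Tff2 (0.05, adjusted p = 0.918) and Pgc (0.16, adjusted p = 0.684) ranked 7 and 8 by control signal. Of 8 chief cell markers 1 rose, the pepsinogen gene Pga5, and the list did not pass (camera adjusted p = 0.0676). Cblif, which encodes gastric intrinsic factor, differed by 0.17 (SE 0.29, adjusted p = 0.882). Of 13 parietal cell markers none was called with limma, 1 was higher when adjusted over the list alone, and all 13 lay above 0 (median 0.34, camera adjusted p = 0.00132, adjusted p = 0.47 with an estimated correlation). The parietal call was lost without Satin replicate 1 (0.157) and with the Gapdh covariate (0.104). The proton pump genes Atp4a and Atp4b differed by 0.59 (SE 0.29, adjusted p = 0.45) and 0.34 (SE 0.20, adjusted p = 0.537), and the anion exchanger gene Slc4a2 by 0.93 (adjusted p = 0.0794, and 0.0186 without Satin replicate 2) and Esrrg by 1.02 (adjusted p = 0.201, and 0.0454 without BL6 replicate 2). Atp4a passed with the arrays as deposited, with the hybridization controls and in the fit of 4 arrays.

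Enteroendocrine genes were lower in Satin. Of 21 markers tested, 3 fell and 18 did not pass, and adjusted over the list alone 7 fell and 1 rose. The median was -0.50, with camera adjusted p = 0.000139 and adjusted p = 0.393 with an estimated correlation. Chgb and Chga, granins of endocrine secretory granules, fell by 2.35 (SE 0.33, adjusted p = 0.0107) and 1.12 (SE 0.20, adjusted p = 0.0297), and Gast, the gastrin gene of antral G cells, fell by 1.40 (SE 0.22, 2.64-fold, adjusted p = 0.0183), from 12.05 in the controls to 10.66 ± 0.63. Somatostatin (Sst) differed by -0.60 (SE 0.35, adjusted p = 0.543) and ghrelin (Ghrl) by -0.50 (SE 0.22, adjusted p = 0.403). When Beige replicate 1, Beige replicate 2 or Satin replicate 1 was left out, the adjusted p was 0.145, 0.138 and 0.113 for Gast and 0.071, 0.0854 and 0.0672 for Chgb. For Chga it was 0.0505, 0.11, 0.191 and 0.125 without BL6 replicate 1, Beige replicate 1, Satin replicate 1 and Satin replicate 2. Gast was also lost with median centring (0.0533), without a filter (0.0515), without the trend (0.133) and with the Gapdh covariate (0.11). Chgb was lost without the trend (0.0827), with the robust option (0.0591) and with the Gapdh covariate (0.0542), and Chga in 7 settings besides the omissions, with an adjusted p of up to 0.14. The list median lay at 0.01 when scaled to the hybridization controls, which is -0.48 relative to all genes.

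Smooth muscle genes were lower in Satin, with all 16 members below 0 and a median of -0.81 (camera adjusted p = 1.51e-12, adjusted p = 0.393 with an estimated correlation). The 4 that fell were Des, the desmin gene (-1.53, SE 0.20, adjusted p = 0.00756), Tpm2 (-0.95, adjusted p = 0.0149), Smtn (-0.89, adjusted p = 0.0282) and Actg2, the enteric smooth muscle actin (-0.97, adjusted p = 0.0396), and 13 fell when adjusted over the list alone. Other probe sets, all with a lower signal, gave 0.39 for Des and -0.94, -0.06 and 0.43 for Tpm2. With Beige replicate 1, Beige replicate 2 and Satin replicate 1 left out in turn, Des had an adjusted p of 0.0851, 0.0682 and 0.0655. For Tpm2 it was 0.145, 0.0854 and 0.209, for Smtn 0.145, 0.141 and 0.288, and for Actg2 0.188, 0.195 and 0.386. Smtn and Actg2 were also lost without Satin replicate 2 (0.14 and 0.0577). Other settings ended the call of Des in 3 (0.198), Tpm2 in 6 (0.367), Smtn in 5 (0.343) and Actg2 in 9 (0.208), with the highest adjusted p in brackets, mainly other scalings, the mean of probe sets, no trend and the Gapdh covariate. Beyond these 9, the replicate number as a block ended the call of Actg2 too. The enteric neuron and glia markers, from the same wall, had a median of -0.31, 0 of 11 called and a camera adjusted p = 0.394. That list was lower as deposited (median relative to all genes -0.46, camera adjusted p = 0.0251) and with the hybridization controls (-0.50, 0.0157), while with median centring it did not pass (-0.46, 0.0668). Its mean was 6.03 to 6.38 on the arrays, near the filter, where differences are understated.

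Intestinal epithelium markers were lower as a list (20 tested, 2 fell, also when adjusted over the list alone, median -0.29, camera adjusted p = 0.0488, adjusted p = 0.538 with an estimated correlation). The pair was Fabp2 and Rbp2, a retinol binding protein (-1.17, adjusted p = 0.0469), and Rbp2 was lost without Beige replicate 1 (0.221), Beige replicate 2 (0.188) or Satin replicate 1 (0.424), and in 9 other settings, with an adjusted p of up to 0.186. The list call was lost without BL6 replicate 2 (0.221), Beige replicate 1 (0.09), Beige replicate 2 (0.0823) or Satin replicate 1 (0.752, with a median of 0.09). It was also lost with a pseudocount of 100 (0.0571), with the mean of probe sets (0.0518) and without the trend (0.0942). The list mean was 7.13 on Satin replicate 1 and 8.36 on Satin replicate 2, against 8.05 to 8.68 on the control arrays.

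Proliferation genes were higher, with 25 of 27 members above 0 (median 0.31, camera adjusted p = 4.63e-06, adjusted p = 0.393 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme, rose by 0.81 (SE 0.16, adjusted p = 0.0413), and 4 members were higher when adjusted over the list alone. Ube2c was lost without BL6 replicate 1 (0.0506), Beige replicate 1 (0.166), Beige replicate 2 (0.155), Satin replicate 1 (0.361) or Satin replicate 2 (0.275), and in 5 other settings (up to 0.15). Beyond these 5, the replicate number as a block ended the call of Ube2c too. Oxidative phosphorylation genes were higher with 0 of 22 called by limma and 1 higher when adjusted over the list alone (median 0.29, 18 above 0, camera adjusted p = 8.58e-05, adjusted p = 0.393 with an estimated correlation). The call was kept in all 21 settings. The BL6 arrays had the lowest list means and Satin replicate 1 the highest, while Satin replicate 2 lay at the level of Beige. The list mean was 10.62 and 10.70 in BL6, 10.92 on both Beige arrays, and 11.15 and 10.92 in Satin, and the list did not pass against Beige (0.0682). The ATP synthase gene Atp5a1 (0.66, adjusted p = 0.0573) and Ndufb8 of complex I (0.45, adjusted p = 0.236) had its smallest p, and Atp5a1 passed without BL6 replicate 2 (0.0201). Gastric transcription factor genes were higher with 0 of 18 called and 3 higher when adjusted over the list alone (median 0.30, camera adjusted p = 0.00409, adjusted p = 0.393 with an estimated correlation). Sox21 differed by 0.84 (adjusted p = 0.0641, and 0.0391 without BL6 replicate 2) and Foxa1 by 0.64 (adjusted p = 0.0735, and 0.046 without BL6 replicate 1). Cholesterol synthesis genes were lower with 0 of 16 called and 2 lower when adjusted over the list alone (median -0.32, camera adjusted p = 0.00132, adjusted p = 0.393 with an estimated correlation), with Msmo1 at -0.71 (adjusted p = 0.0798) and Sc5d at -0.83 (adjusted p = 0.0894), which passed without BL6 replicate 2 (0.0114 and 0.0111). The cholesterol call was lost with the hybridization controls (0.0879).

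B and plasma cell genes were higher (11 tested, Jchain rose, also when adjusted over the list alone, median 0.26, camera adjusted p = 0.0087, adjusted p = 0.47 with an estimated correlation). That call was lost without Beige replicate 2 (0.0789) or Satin replicate 2 (0.513). It was also lost as deposited (0.15), with median centring (0.0668) and with the hybridization controls (0.175), with the mean of probe sets (0.0518), in the 4 arrays (0.148) and with the Gapdh covariate (0.154). Of 13 heat shock genes Hspa1b and Hspa1a rose, also when adjusted over the list alone (median 0.18, camera adjusted p = 0.0338, adjusted p = 0.393 with an estimated correlation). Hspa1a rose by 1.64 (adjusted p = 0.0376) and was lost without Beige replicate 1 (0.192), Beige replicate 2 (0.151), Satin replicate 1 (0.311) or Satin replicate 2 (0.118), and in 5 other settings (up to 0.143). The heat shock call was lost without Beige replicate 2 (0.0789) or Satin replicate 2 (0.0797), with each probe set on its own (0.0835), with their mean (0.0814) and without the trend (0.0913). Mast cell genes had 0 of 10 called, also when adjusted over the list alone (median 0.29, camera adjusted p = 0.0399, adjusted p = 0.393 with an estimated correlation), and were lost without BL6 replicate 2 (0.116) or Satin replicate 2 (0.185). The mast cell call was also lost as deposited (0.239), with median centring (0.087) and with the hybridization controls (0.372). It was lost with the 50% filter (0.0521), with each probe set on its own (0.105), with their mean (0.183) and in the 4 arrays (0.371). The proteoglycan gene Srgn (0.42, adjusted p = 0.348) and the receptor gene Kit (0.43, adjusted p = 0.508) had the smallest p among them. Of the 32 lists tested, 13 passed with the preset correlation and 0 with an estimated one. The estimated version has only 3 residual degrees of freedom. Of the 13 lists, smooth muscle had the highest estimated correlation, 0.39. It was 0.34 for parietal, 0.34 for B and plasma cell and 0.21 for oxidative phosphorylation genes. Only the enteroendocrine, mast cell and gastric transcription factor lists among the 13 had one below 0. Where the correlation exceeds the preset 0.01, the camera p at the preset can be too small. With the estimate the unadjusted p rose even below 0, as for enteroendocrine genes (correlation -0.0167, p from 1.74e-05 to 0.0181). The lack of calls with an estimated correlation therefore cannot show whether correlation within the lists accounts for the 13 calls. Against each control strain by itself 6 of the 13 passed, the smooth muscle, enteroendocrine, antral gland, parietal, proliferation and cholesterol lists, while the intestinal and mast cell lists passed against neither. At an unadjusted p under 0.05 with an estimated correlation, the antral gland, enteroendocrine and gastric transcription factor lists had 0.0464, 0.0181 and 0.038.

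The other lists did not pass in this comparison. Called members were found among adipocyte markers (Scd1 of 12, camera adjusted p = 0.456) and fibroblast and matrix genes (Igfbp4 of 18, 0.86 higher, camera adjusted p = 0.0532). They were also found among secretory granule and exocytosis genes (Rab3b 1.74 higher and Sytl2 at -0.74 of 19, camera adjusted p = 0.112), squamous forestomach markers (S100a14 at -0.97 of 13, camera adjusted p = 0.663) and xenobiotic and glutathione genes (Adh7, Nqo1 at -1.18 and Aldh1a1 0.86 higher of 27, camera adjusted p = 0.733). Of the blood cell markers 1 was tested, the platelet gene Pf4, which fell by 1.07 (adjusted p = 0.0204). Leaving out Beige replicate 1, Beige replicate 2 and Satin replicate 1 gave an adjusted p of 0.107, 0.0878 and 0.0761 for Nqo1, a quinone reductase, and 0.19, 0.155 and 0.368 for S100a14. With the same 3 arrays and then Satin replicate 2 left out in turn, it was 0.199, 0.127, 0.309 and 0.12 for Igfbp4 and 0.187, 0.13, 0.309 and 0.174 for Sytl2. In the same order it was 0.187, 0.178, 0.358 and 0.0672 for Aldh1a1, and 0.121, 0.102, 0.131 and 0.143 for Pf4. Rab3b was lost without Satin replicate 1 (0.0866) or Satin replicate 2 (0.079). Other settings ended the call of Nqo1 in 3 (0.0997), S100a14 in 7 (0.21), Igfbp4 in 5 (0.187), Sytl2 in 5 (0.683), Aldh1a1 in 3 (0.187) and Pf4 in 5 (0.12), with the highest adjusted p in brackets.

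No member was called by limma among isthmus and antral stem cell markers (14, camera adjusted p = 0.0733), MHC class I and II genes (14, camera adjusted p = 0.0556), interferon response genes (18, camera adjusted p = 0.073) and mucin O-glycosylation genes (20, camera adjusted p = 0.105). The same holds for T and NK cell genes (6, camera adjusted p = 0.427), macrophage and myeloid genes (19, camera adjusted p = 0.473) and lysosome genes (26, camera adjusted p = 0.733). It also holds for endoplasmic reticulum stress genes (26, camera adjusted p = 0.588), core clock genes (16, camera adjusted p = 0.994), immediate early genes (18, camera adjusted p = 0.66) and sex-linked genes (4, camera adjusted p = 0.638). Adjusted over the list alone, 3 MHC genes and 1 stem cell marker were higher, 2 endoplasmic reticulum stress genes and 1 immediate early gene were lower, 2 squamous markers were lower, 1 fibroblast gene was higher and 1 lower, and the other counts were as over all genes. The members with the smallest p included the stem cell marker Stmn1 (0.63, adjusted p = 0.0732), the invariant chain gene Cd74 (0.65, adjusted p = 0.12), and the chaperone gene Pdia6 (-0.97, adjusted p = 0.0799, and 0.0256 without Satin replicate 2). Others were the protease gene Ctsh (-0.83, adjusted p = 0.0848, and 0.0367 without BL6 replicate 2), the phosphatase gene Dusp1 (-0.80, adjusted p = 0.0891), the sialyltransferase gene St3gal6 (0.66, adjusted p = 0.129) and the mannose receptor gene Mrc1 (-0.58, adjusted p = 0.224). The median, mean and test differed in sign for the lysosome list (0.04, -0.04 and lower), the squamous list (-0.03, 0.02 and lower) and the xenobiotic list (0.10, -0.04 and higher). The same was found for the clock list (-0.04, -0.01 and higher) and the acinar list below.

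Markers of pancreatic acinar cells separated arrays of 1 strain. The mean of the 15 acinar genes was 6.91 and 12.31 on the BL6 arrays, 7.28 and 9.39 on the Beige arrays, and 6.76 and 11.11 on the Satin arrays, replicate 2 being the higher in each pair. In Satin against both controls the list had 0 of 15 called by limma, also when adjusted over the list alone (median 0.27, mean -0.04, camera lower with adjusted p = 0.889). Without BL6 replicate 1 it was lower (0.0059), without BL6 replicate 2 higher (0.0201), without Satin replicate 1 higher (0.00032) and without Satin replicate 2 lower (0.000182). By camera the acinar list was lower as deposited (0.0024), with the hybridization controls (0.00148) and with the Gapdh covariate (6.14e-06). With the acinar mean as a covariate no count of called genes moved by more than 1.5 times. In 4 arrays, without replicate 2 of BL6 and of Satin, 487 genes were called in Satin against both controls.

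**Figure D2:**
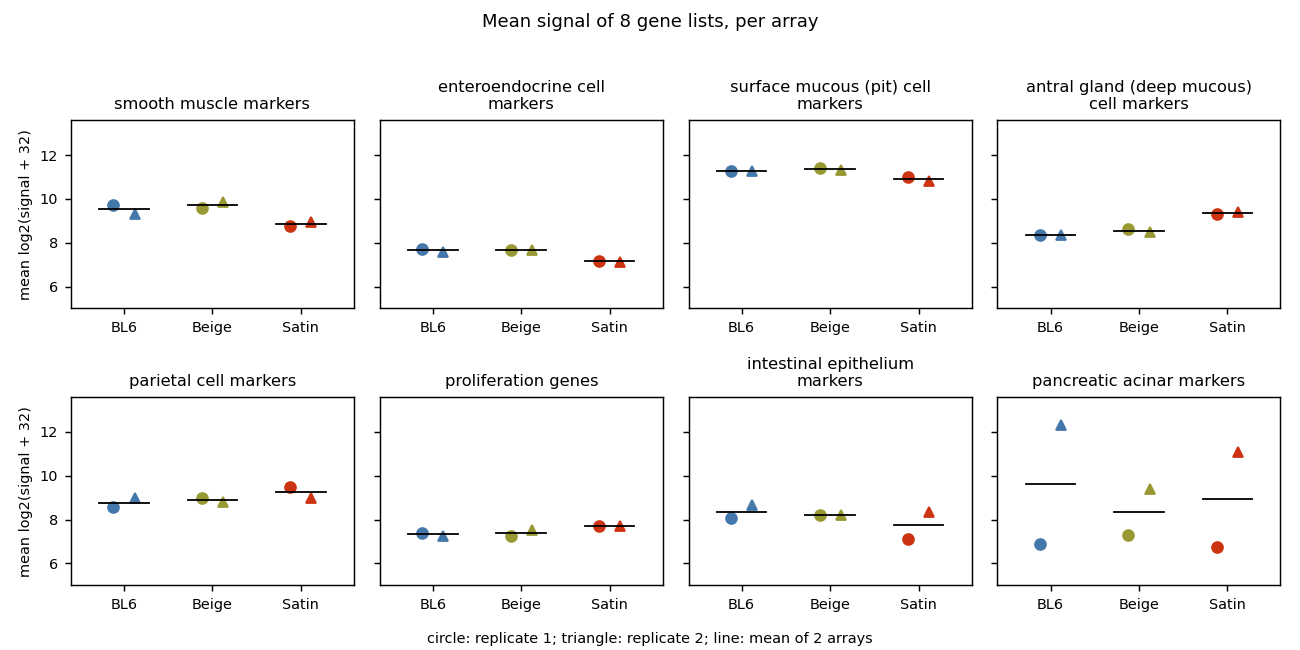
Mean log2(signal + 32) of the tested members of 8 gene lists, per array, for the 2 arrays each of BL6, Beige and Satin (circle, replicate 1, and triangle, replicate 2), with the strain mean as a line. The smooth muscle and enteroendocrine means are lower on both Satin arrays than on all 4 control arrays, while the acinar mean runs from 6.76 to 12.31 with the arrays of 1 strain far apart.

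Against Beige alone, Satin had 85 called genes, 21 higher and 64 lower, and 991 with an unadjusted p under 0.05. Muc5ac (-4.36, SE 0.18, adjusted p = 4.32e-06) and Fabp2 (-4.71, SE 0.23, adjusted p = 1.51e-05) fell, while Chil4 rose by 7.07 (SE 0.27, adjusted p = 4.32e-06) and Igha by 4.46 (SE 0.38, adjusted p = 0.000798). Cldn3 (4.24), Bpifb1 (4.12), Cap1 (3.72), Pga5 (2.93), the heat shock genes Hspa1b (2.78) and Hspa1a (2.19), Jchain (2.39), Sdc4 (2.06), Rab3b (1.94), a vesicle GTPase, and S100a8 (1.93) rose. Cybrd1 (-2.94), Slurp1 (-2.73), Stk25 (-2.62), Rpgrip1 (-2.45), C1qtnf12 (-2.43), Hsd17b2 (-2.42), Krt7 (-2.39), Rep15, a Rab15 effector (-2.17), and Adh7 (-2.10) fell. Gast (2.83-fold, adjusted p = 0.033) and Chgb (-2.04, adjusted p = 0.0488) fell, and Chga differed by -0.96 (adjusted p = 0.127). Foxq1 differed by 0.80 (SE 0.19, adjusted p = 0.109). Omission of Beige replicate 1, Beige replicate 2 and Satin replicate 1 gave an adjusted p of 0.428, 0.238 and 0.121 for Gast, 0.369, 0.279 and 0.23 for Chgb, and 0.311, 0.189 and 0.058 for Hspa1b. With the same 3 arrays and then Satin replicate 2 left out in turn, it was 0.406, 0.199, 0.161 and 0.0649 for Hspa1a and 0.29, 0.235, 0.0978 and 0.0699 for Jchain. In the same order it was 0.197, 0.0735, 0.0978 and 0.0813 for Rab3b, and 0.402, 0.199, 0.265 and 0.255 for S100a8. For omission of Beige replicate 1 and Beige replicate 2 it was 0.197 and 0.194 for Bpifb1, 0.279 and 0.113 for Cldn3, and 0.197 and 0.136 for Slurp1. Likewise it was 0.136 and 0.053 for Stk25, 0.197 and 0.113 for Krt7, 0.188 and 0.0945 for Adh7, and 0.0591 and 0.0807 for Sdc4. Without Beige replicate 1 alone Igha (0.0627) and Hsd17b2 (0.0591) were lost. Other settings, the replicate block left aside, ended the call of Chgb in 9 (0.232), S100a8 in 7 (0.223), Gast in 6 (0.211), Jchain in 5 (0.176), Cldn3 in 3 (0.156), Hspa1a in 3 (0.144), Hspa1b in 3 (0.129) and Bpifb1 in 2 (0.15), and of Adh7 in 1 (0.0584), Krt7 in 1 (0.0625), Rab3b in 1 (0.0664), Rpgrip1 in 1 (0.316), Sdc4 in 1 (0.242) and Slurp1 in 1 (0.0664), with the highest adjusted p in brackets. The split was 151 higher and 40 lower as deposited, 145 and 37 with the hybridization controls, and 20 and 32 with median centring. The count was 134 without BL6 replicate 1, 147 without BL6 replicate 2, 9 without Beige replicate 1, 13 without Beige replicate 2 and 30 without Satin replicate 1.

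Against Beige 10 lists passed with camera and 0 with an estimated correlation. Lower lists were smooth muscle (3 of 16 called, 13 when adjusted over the list alone, adjusted p = 6.05e-14, adjusted p = 0.386 with an estimated correlation), enteroendocrine (2 of 21 called, 8 lower and 1 higher when adjusted over the list alone, adjusted p = 0.000233 and 0.386) and cholesterol synthesis (0 of 16 and 1, adjusted p = 0.00209 and 0.41). The pit cell list (2 of 18, with 4 lower and 1 higher, adjusted p = 0.0126 and 0.461) and the interferon response list (0 of 18 and 0, adjusted p = 0.025 and 0.45) were lower as well. Higher lists, in the same order of values, were proliferation (0 of 27 and 0, adjusted p = 0.000168 and 0.386), gastric transcription factors (0 of 18 and 3, adjusted p = 0.000757 and 0.386), and antral gland (1 of 8 and 1, adjusted p = 0.0126 and 0.386). The others were parietal (0 of 13 and 1, adjusted p = 0.0126 and 0.544) and heat shock (2 of 13 and 2, adjusted p = 0.0248 and 0.386). Calls were lost without Beige replicate 2 for the antral gland (0.148), parietal (0.167) and heat shock (0.105) lists. They were lost without Satin replicate 1 for the parietal list (0.537), without Beige replicate 1 for the interferon list (0.0892), and without Satin replicate 2 for the interferon (0.0594), pit cell (0.0891) and heat shock (0.0502) lists. The heat shock list was lost with each probe set on its own (0.0748), with their mean (0.0798) and without the trend (0.0558). The interferon list was lost with the mean of probe sets (0.0502), in the 4 arrays (0.106) and with the Gapdh covariate (0.0734), and the parietal list with that covariate (0.0515). Lists that did not pass here did so in some of 22 other settings, counting omissions. The macrophage and myeloid list (adjusted p = 0.0501 here) was lower in 12, down to 0.00197, and the intestinal list (0.0682) lower in 8, down to 9.07e-13. The B and plasma cell list (0.0507) was higher in 9, down to 4.97e-05, and the oxidative phosphorylation list (0.0682) higher in 6, down to 0.00021. For any other list there were at most 4.

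Against BL6 alone, Satin had 70 called genes, 21 higher and 49 lower, and 1181 with an unadjusted p under 0.05. Muc5ac (-4.29, SE 0.18, adjusted p = 9.85e-06) and Fabp2 (-4.56, SE 0.23, adjusted p = 2.01e-05) fell, and Chil4 rose by 5.88 (SE 0.27, adjusted p = 1.21e-05). Bpifb1 (4.64), Cldn3 (3.95), Cap1 (3.51), Pga5 (3.28), Scd1 (2.77), Igha (2.23), Ces1g (1.98), Sdc4 (1.73), Rab3b (1.54), Grp, the gastrin-releasing peptide gene (1.54), and Nedd4, a ubiquitin ligase (1.43), rose. Rpgrip1 (-2.99), Cybrd1 (-2.74), Stk25 (-2.56), Slurp1 (-2.33), C1qtnf12 (-2.32), Ly6g6c (-2.06), Adh7 (-1.99), Hsd17b2 (-1.96) and Adi1, an enzyme of methionine salvage (-1.93), fell. Other probe sets of Nedd4 gave -0.04 and 0.29 against both controls, and those of Adi1 gave -2.36 and 0.81. Chgb (-2.66, adjusted p = 0.0184) and Chga (-1.28, adjusted p = 0.0449) fell, and Gast differed by -1.30 (adjusted p = 0.066). Chga was no longer called with any 1 of the 6 arrays left out. Its adjusted p was 0.135 and 0.0557 without BL6 replicates 1 and 2, 0.0674 and 0.0619 without Beige replicates 1 and 2, and 0.213 and 0.132 without Satin replicates 1 and 2. Gast was called without Satin replicate 2 (0.00446). Without BL6 replicate 1, Beige replicate 1 and Beige replicate 2 the adjusted p was 0.0587, 0.0894 and 0.0892 for Chgb, which was also lost without Satin replicate 1 (0.0592), and 0.0578, 0.0927 and 0.0906 for Scd1. For Slurp1 it was 0.0578, 0.0927 and 0.0907. Leaving out Beige replicate 1, Beige replicate 2 and Satin replicate 1 gave 0.0883, 0.0892 and 0.0618 for Cldn3. With the same 3 arrays and then Satin replicate 2 left out in turn, it was 0.157, 0.156, 0.166 and 0.0713 for Igha and 0.106, 0.107, 0.299 and 0.0697 for Grp. In the same order it was 0.127, 0.123, 0.398 and 0.104 for Ces1g, which was also lost without BL6 replicate 1 (0.124). Sdc4 was lost without Satin replicate 1 (0.0618). Rab3b was lost without each array, at 0.0613 and 0.0575 without BL6 replicates 1 and 2, 0.0883 and 0.0892 without Beige replicates 1 and 2, and 0.245 and 0.219 without Satin replicates 1 and 2. Other settings, the replicate block left aside, ended the call of Chga in 10 (0.236), Igha in 8 (0.188), Rab3b in 8 (0.134), Ces1g in 7 (0.369), Chgb in 6 (0.194), Cldn3 in 6 (0.172), Grp in 6 (0.129) and Scd1 in 6 (0.204), with the highest adjusted p in brackets. They also did so for Slurp1 in 5 (0.129), Adh7 in 3 (0.0858), Bpifb1 in 3 (0.113), Nedd4 in 3 (0.24), Sdc4 in 2 (0.328), Adi1 in 1 (0.0659), Hsd17b2 in 1 (0.0523), Ly6g6c in 1 (0.0531) and Rpgrip1 in 1 (0.27). The split was 1834 higher and 41 lower as deposited, 3380 and 36 with the hybridization controls, and 24 and 21 with median centring. The count was 39 without BL6 replicate 1, 225 without BL6 replicate 2, 22 without Beige replicate 1, 22 without Beige replicate 2 and 33 without Satin replicate 1.

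Against BL6 9 lists passed with camera and 0 with an estimated correlation. Lower lists were smooth muscle (2 of 16 called, 10 when adjusted over the list alone, adjusted p = 1.2e-08, adjusted p = 0.498 with an estimated correlation), enteroendocrine (2 of 21 called, 6 lower and 1 higher when adjusted over the list alone, adjusted p = 0.00124 and 0.498) and cholesterol synthesis (0 of 16 and 1, adjusted p = 0.00996 and 0.505). Higher lists, in the same order of values, were oxidative phosphorylation (0 of 22 and 7, adjusted p = 1.26e-07 and 0.498), proliferation (0 of 27 and 4, adjusted p = 5.89e-06 and 0.498), and antral gland (1 of 8 and 2, adjusted p = 0.000296 and 0.498). The others were parietal (0 of 13 and 0, adjusted p = 0.00124 and 0.505), B and plasma cells (0 of 11 and 1, adjusted p = 0.00527 and 0.505) and MHC (0 of 14 and 3, adjusted p = 0.018 and 0.59). Calls were lost without BL6 replicate 1 for the parietal (0.0588) and plasma cell (0.0936) lists, and without BL6 replicate 2 for the MHC list (0.0534). They were lost without Satin replicate 1 for the parietal list (0.0726), and without Satin replicate 2 for the plasma cell (0.342) and MHC (0.355) lists. As deposited, with median centring and with the hybridization controls, the adjusted p was 0.111, 0.0556 and 0.191 for the plasma cell list, 0.0638, 0.075 and 0.0707 for the MHC list, and 0.246, 0.103 and 0.397 for the cholesterol list. With the Gapdh covariate these lists were at 0.428, 0.0704 and 0.271 and the parietal list at 0.317. The cholesterol list was also lost with the mean of probe sets (0.0697) and the MHC list in the 4 arrays (0.387). Of 22 other settings, counting omissions, the intestinal list passed in 12, the acinar list in 8, the adipocyte list in 6, the chief cell, gastric transcription factor and heat shock lists in 5 each, and any other list that did not pass here in at most 3. As deposited, with median centring and with the hybridization controls, the intestinal list was lower (1.82e-05, 0.0063 and 1.7e-05), as was the acinar list (5.96e-07, 0.0161 and 7.49e-08). The gastric transcription factor (0.00371, 0.00994 and 0.00153) and heat shock (0.0153, 0.0456 and 0.00666) lists were higher.

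Called against Beige and against BL6 in the same direction were 55 genes, 12 higher and 43 lower, and 0 genes were called in opposite directions. Apart from genes named above, the 12 that were higher included Btbd3, a BTB domain protein (1.22 against both controls), Gnb1, a G protein subunit (1.21), and the transcription factor gene Sox4 (1.12). In the comparison with both controls, the adjusted p without Beige replicate 1, Beige replicate 2 and Satin replicate 1 was 0.121, 0.0756 and 0.177 for Btbd3, 0.0632, 0.0692 and 0.103 for Gnb1, and 0.0537, 0.0682 and 0.131 for Sox4, which was also lost without Satin replicate 2 (0.0592). Other settings ended the call of Btbd3 in 2 (0.0997), Gnb1 in 2 (0.159) and Sox4 in 2 (0.187), with the highest adjusted p in brackets. Unchanged groups that share the Satin arrays gave a mean overlap of 0.34 genes and at most 5 in 100 simulations, and independent lists of these lengths would share 0.0469 higher and 0.334 lower genes. The simulated noise was independent between genes, so it held no deviation of a whole Satin array. It cannot show how much overlap such a deviation would give. Part of the overlap may come from the shared Satin arrays, which are too few to split. The overlap was 31 without BL6 replicate 1, 87 without BL6 replicate 2, 9 without Beige replicate 1, 12 without Beige replicate 2 and 26 without Satin replicate 1. Calls did not gather on a chromosome, with a smallest adjusted p from Fisher's exact test of 1 against both controls, 0.75 against Beige and 0.694 against BL6. Chromosome 13, which carries Foxq1 and Lyst, held 4 called genes of 334 tested, against 1.43% of all genes.

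The comparison of the control strains asked how far antral expression varies without the satin mutation. Beige and BL6 differed in 0 genes by limma, with 484 at an unadjusted p under 0.05 and a smallest adjusted p of 0.743. The 5 genes with the smallest p were Fen1, a flap endonuclease (-1.01 in Beige), Igha (-2.23), Rps19, a ribosomal protein (0.84), Sf3b5, a splicing factor (1.57), and Wdfy1 (-1.42). Igha was called without BL6 replicate 1 (0.00287), and Sf3b5 (0.0441) and Wdfy1 (0.0499) without BL6 replicate 2. Muc5ac differed by 0.06, Gast by 0.20 and Foxq1 by -0.52 (adjusted p = 0.864). The count was 5 without BL6 replicate 1 and 10 without BL6 replicate 2, 3 as deposited and 35 with the hybridization controls.

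In Beige against BL6, 5 lists passed with camera and 0 with an estimated correlation (adjusted p = 0.885 for each), and none of them held a called member, also when adjusted over the list alone. Oxidative phosphorylation genes (median 0.28, adjusted p = 3.56e-06), macrophage and myeloid genes (0.35, adjusted p = 0.00558), adipocyte markers (0.42, adjusted p = 0.00594) and smooth muscle markers (0.20, adjusted p = 0.0389) were higher in Beige, and acinar markers were lower (-1.40, adjusted p = 0.0234). The adipocyte call was lost without BL6 replicate 1 (0.927) or Beige replicate 1 (0.0504), and the macrophage call without BL6 replicate 2 (0.234) or Beige replicate 2 (0.0624). The muscle call was lost without BL6 replicate 2 (0.947) or Beige replicate 2 (0.541), and the acinar call without BL6 replicate 2 (0.234) or Beige replicate 1 (0.573). With a pseudocount of 1, without a filter, with the 50% filter and without the trend, the muscle list was at 0.0591, 0.0505, 0.0668 and 0.0817 and the acinar list at 0.0853, 0.0505, 0.0704 and 0.0756. With the acinar covariate the muscle list was at 0.148. The adipocyte call was also lost without a filter (0.0631) and the macrophage call in the 4 arrays (0.0868). Of the lists that did not pass here, immediate early genes passed in 4 of 22 other settings and any other in at most 2. Adipoq, an adipocyte hormone gene, was at 5.05 on BL6 replicate 1 and at 8.51 to 8.73 on the other control arrays.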

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

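The alternatives chosen only after the results were seen are the scaling to the hybridization controls, the acinar and Gapdh covariates and the fit of 4 arrays. Of the 134 genes called in Satin against both controls, 133 kept their direction under every setting that tested them, which is 20 settings for S100a8, Ces1g, Rnase2a and Trim34a and 21 for the others, and 18 were called under all 21. The exception is Klhl7, which ran from -1.06 to 0.07. Those 18 were Chil4, Cap1, Igha and Pga5 (higher) and Fabp2, Muc5ac, Cybrd1, Stk25, C1qtnf12, Hsd17b2, Krt7, Adh7, Ly6g6c, Rep15, Akr1e1, Ncmap, Oit1 and Adi1 (lower). Muc5ac ran from -4.44 to -3.89 and Chil4 from 5.63 to 7.21. With the preset correlation, the smooth muscle, enteroendocrine, antral gland, proliferation, oxidative phosphorylation and gastric transcription factor lists stayed past the threshold in Satin against both controls in all 21 settings. Signals at the top of the range and near the filter limit what can be seen of Gkn1, Gkn2, Tff1, Tff2, Pgc and Muc5ac, of Chil4 at both ends, and of Lyst and Xist.

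Counts of called genes are given in the order Satin against both controls, against Beige, against BL6, Beige against BL6, and the overlap, where they moved by over 1.5 times. As deposited they were 1531, 191, 1875, 3 and 170, and with the hybridization controls 2497, 182, 3416, 35 and 167. Both settings keep the brighter signal of the Satin arrays that quantile normalization removes. Median centring gave 52 and 45 against Beige and BL6 and an overlap of 33. A pseudocount of 1 gave 46 against BL6. Without a filter, with more genes tested, the counts were 43 against Beige, 33 against BL6 and 27 for the overlap. The mean of a gene's probe sets gave 37, 22 and 22 for the same. Without the trend the counts were 34, 18, 12 and an overlap of 11, and with the robust option 223, 128 and 119. Fitting only the strains compared gave 136, 21 and an overlap of 20. The 4 arrays gave 487, 342, 480, 122 and 217, with 1 residual pair only. The Gapdh covariate gave 60 against both controls, 29 against BL6, 6 for Beige against BL6 and an overlap of 20. The cause of the other moves was not tested.

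With each array left out in turn, leaving fewer arrays, the counts ran from 28 to 299, 9 to 147, 22 to 225, 0 to 10, and 9 to 87 for the overlap. Of 351 results for a named gene in a comparison, 58 lost their call without Beige replicate 1, 55 without Beige replicate 2, 47 without Satin replicate 1, 30 without Satin replicate 2, 12 without BL6 replicate 1 and 2 without BL6 replicate 2, and 0 of those called changed direction under any setting. Small differences that were not called could change sign, as Muc5ac did in Beige against BL6 (-0.16 to 0.30).

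With an estimated correlation, tested on 3 residual degrees of freedom only, the lists past the threshold were 0, 0, 0 and 0 in the 4 comparisons. The mean of a gene's probe sets gave 8 lists for Satin against both controls. For Beige against BL6 the lists were 3 with a pseudocount of 1, 2 without a filter, 3 with the 50% filter, 3 without the trend, 3 with the acinar covariate and 9 with the Gapdh covariate. Without 1 array the lists ran from 7 to 16 against Beige and from 2 to 9 for Beige against BL6.

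Some list tests changed direction without 1 array. The intestinal list against both controls did so without Satin replicate 1 (0.752), and smooth muscle in Beige against BL6 without BL6 replicate 2 (0.947). They kept their direction under the other omissions, down to 7.46e-09 for the intestinal list and 5.14e-06 for smooth muscle. For pancreatic acinar markers, which went either way, the camera adjusted p over the 6 omissions ran from 0.000182 to 0.702 against both controls, 1.56e-06 to 0.883 against Beige, 2.57e-08 to 0.313 against BL6, and 5.95e-14 to 0.573 for Beige against BL6. In the 4 arrays smooth muscle was reversed in Beige against BL6 (0.831). The 4 arrays were chosen by the acinar list, so its reversals there against Beige (1.61e-07) and in Beige against BL6 (1.03e-07) say nothing about the strains, nor does its test with its own mean as a covariate. With the Gapdh covariate the adipocyte list was reversed in Beige against BL6 (0.916).

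Other settings also gave list calls in Satin against both controls that the first fit had not. Interferon genes were lower as deposited (0.00889), with median centring (0.00979) and with the hybridization controls (0.0054), and in 2 more settings. Fibroblast genes passed in 5 settings (0.0186 to 0.0483) and chief cell genes in 3 (2.11e-05 to 0.0475). MHC genes passed without a filter (0.0468), and adipocyte (0.0186) and macrophage (0.032) genes in the 4 arrays. More lists passed with 1 array left out. Without BL6 replicate 2 these were chief cell (0.0228), fibroblast (0.00815), adipocyte (0.00919) and interferon (0.0368) genes. Without Beige replicate 1 they were chief cell (0.0457), fibroblast (0.0184) and MHC (0.0172) genes. Without Satin replicate 1 they were fibroblast and adipocyte (0.0357 each), stem cell (0.0308), MHC (0.000447) and mucin O-glycosylation (0.0447) genes. Without Satin replicate 2 they were chief cell (0.00713) and macrophage (0.0351) genes.

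Nothing in the labels ties the replicate numbers to a batch, and there are only 2 numbers. Whether same-numbered arrays share a batch therefore stays open. With the replicate number as a block the counts were 123, 86, 49, 0 and an overlap of 43, all within 1.5 times. Of the 351 named results 10 were no longer called, Actg2 and Ube2c of them against both controls, and 2 newly called. Of the list tests, pit cells against both controls were no longer called (0.0504). Newly called were plasma cells, macrophages (0.0445 each) and acinar genes (0.025) against Beige, adipocyte (0.0444), chief cell (0.0479), intestinal and acinar genes (0.0234 each) against BL6, and immediate early genes in Beige against BL6 (0.0463). Deviations of same-numbered arrays correlated, across genes, at 0.118, 0.270 and 0.188 between the pairs of strains, and at 0.042, 0.138 and 0.110 without the acinar genes.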

Other observations

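The tests chosen only after the result was seen are those of the other pit cell markers, of BL6 replicate 1 and the Gapdh ratio, of strain and scaling for the acinar genes, of islet genes in single arrays, and of the muscle genes. The genes of the next paragraph were also chosen after their values were seen.

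Some further genes were picked from the calls. Krt20, a keratin of surface epithelial cells, fell by 1.63 (SE 0.21, adjusted p = 0.00711), the villin-like gene Vill by 1.58 (SE 0.25, adjusted p = 0.0173), the annexin gene Anxa13 by 1.39 (SE 0.20, adjusted p = 0.0113), Psapl1, a saposin-like gene, by 1.31 (SE 0.14, adjusted p = 0.00253), and Rep15, a Rab15 effector, by 1.91 (SE 0.13, adjusted p = 0.000157). Higher genes included Grp, the gastrin-releasing peptide gene, by 1.42 (SE 0.22, adjusted p = 0.0145), the carbonic anhydrase gene Car9 by 1.24 (SE 0.21, adjusted p = 0.0228) and Tm4sf5 by 1.29 (SE 0.20, adjusted p = 0.0145). Rep15 and Psapl1 were called without each of the 6 arrays, and the other 6 genes under 3 of the 6 omissions.

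The goblet cell products Zg16, Fcgbp and Clca1 in the intestinal list stood apart on 1 array. Zg16 was at 6.57, Fcgbp at 6.76 and Clca1 at 8.72 on Satin replicate 1, against 11.48, 10.44 and 11.60 on Satin replicate 2 and at least 10.27 on each control array.

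For the fall of Muc5ac and the other calls in Satin, a loss of surface mucous cells would lower the other pit markers, but 9 of them with a control signal below 12 had a median of -0.16 (SE 0.32), far from the fall of Muc5ac, so such a loss is argued against as its whole cause. Poor RNA in BL6 replicate 1 is argued against as the whole cause, since without that array 134 genes were called against Beige, where it does not enter, 104 of them among those called against both controls, and Muc5ac differed by -4.21 without it and by -4.10 with the Gapdh ratio as a covariate. That covariate ended 82 calls, whose median size went from 1.04 (median SE 0.181) to 0.97 (0.196) with fewer residual degrees of freedom, and since the ratio is highest on both Satin arrays a part in these stays open. Strain sequence variants under the probes cannot be told apart from expression over the calls as a set, since other probe sets of 47 called genes showed a median share of 0.467 (SE 0.095) of the tested difference, 37 in the called and 10 in the opposite direction, and Muc5ac has a single probe set. The share was over 0.5 in 22 genes and under 0.2 in 14. Low shares came both from other probe sets near the filter, as for Rpgrip1 (mean 5.80), and from brighter ones, as for Nedd4 (9.49). The Foxq1 mutation and the rest of the Satin background are carried together by both Satin mice, and which of them goes with these changes stays open and untested.

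The acinar genes, high on replicate 2 of each strain, were weighed against 3 explanations. A strain difference is argued against, since the gap within a strain reached 5.40 and that between strain means 1.27, and scaling is argued against, since the gap in BL6 was at least 5.40 under 4 scalings. Pancreatic tissue with islets in both high arrays is argued against, since 0 of 4 islet hormone genes were over 1 higher in both. On BL6 replicate 2 alone, Ins2 was 4.34 and Iapp 4.17 higher than on replicate 1, which is consistent with pancreas in that sample, whereas on Satin replicate 2 the second largest islet difference was -0.10. Acinar tissue without islets may still account for Satin replicate 2 and was not tested.

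For the lower smooth muscle genes in Satin, the muscle median relative to all genes stayed at or below -0.72 under 4 scalings. That measure takes out any shift common to all genes, so it cannot test such a shift. The muscle median itself was -0.81 after quantile normalization, -0.65 with median centring, -0.32 as deposited and -0.23 with the hybridization controls. It was thus below 0 under each scaling, while its size depended on the scaling. Poor RNA in BL6 replicate 1 is argued against, since the median was -0.70 without it and -0.81 with it. A thinner share of muscle wall in the dissected tissue cannot be told apart from lower expression. The neuron and glia genes of the wall had a median of -0.31 (SE 0.15 between genes, camera adjusted p = 0.394). That median lies within 2 SE of the -0.40 that a shared loss was taken to need. As deposited and with the hybridization controls the median of the neuron and glia genes was -0.46 and -0.50 relative to all genes. By itself it was -0.03 and -0.002. The list mean was 6.03 to 6.38 on the arrays, near the filter, where differences are understated, a shift common to all genes included. A difference between the strains in muscle itself stays open and untested.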
